A study of Homo sapiens with 63 samples.

How the data were processed

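Total RNA of untreated cultures of 40 human non-Hodgkin lymphoma cell lines was extracted with a column kit, and biotin-labelled cRNA made from 6 ug of it was hybridized to Affymetrix arrays. The deposited table holds 1 value on a log2 scale for each of 54675 probe sets in each of 63 arrays. Per the labels the authors processed the arrays with GCRMA, which corrects for background by probe sequence, normalizes between arrays and summarises the probes of a probe set. Its version, its annotation and the arrays processed together are not given in the sources used here. Values ran from -0.18 to 16.4 and none was missing. Genes without signal read a floor that differs between probe sets, so differences from such a level may understate the true ratio. Arrays have no read depth, and the number of arrays limits the precision.

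Probe sets were named from the platform annotation, with symbols checked through the Entrez identifier, where 0 were updated and 54 did not match. Of the probe sets, 41091 had 1 gene symbol, 1801 had several and 11721 had none, apart from 62 controls. Only those with 1 symbol were used, giving 19775 genes. Where a gene had more than 1 probe set (10523 genes), the one with the highest mean over all arrays stood for it. Probe sets of a gene often disagreed. Among 3026 such genes with an SD of line means of at least 1, the other probe sets all reached an r of 0.8 with the brightest in 818, and in 675 none reached 0.5. Of 155 genes named by rule, 95 had more than 1 probe set, and in 16 of them none of the others reached 0.5, many of those others lying at the floor. Of the fixed lists, 34 members in 17 lists are not analysed here. The 35 genes of the Y chromosome or of X inactivation were never named.

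The test was a linear model on the log2 values with 1 coefficient per line (limma 3.58.1 in R 4.3.3, lmFit and eBayes with a mean-variance trend). Its spread is 1 pooled value per gene with 23 residual degrees of freedom, all from the 20 lines with more than 1 array, and a median within-line SD of 0.163. Genes differing among lines were found with the moderated F test. Differences between 2 lines, between FarageX1 and Farage, and between 1 line and the equally weighted mean of the others were tested with limma's treat against a difference of 1 log2 unit, two-sided. P-values were adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. Replicate numbers do not name a shared culture or day, so no replicate block was used in the main model.

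Gene lists were tested in each line with camera at a preset inter-gene correlation of 0.01, adjusted over all lists and lines. The 25 lists were B-cell surface antigens, B-cell transcription factors and receptor signalling, immunoglobulin genes, germinal-centre genes, activated-B-cell-like genes, plasma-cell genes, MHC class II genes, MHC class I and peptide loading genes, T-cell and NK-cell markers, anaplastic large cell lymphoma genes, myeloid markers, fibroblast and stromal markers, epithelial markers, NF-kB target genes, JAK-STAT and mediastinal B-cell lymphoma genes, interferon-stimulated genes, G1 cell-cycle regulators, BCL2 family and apoptosis genes, proliferation genes, nucleolar and MYC-responsive genes, hypoxia and glycolysis genes, migration and adhesion receptors, drug efflux transporters, cancer-testis antigens and housekeeping genes. The spread of a list was set against 10000 random lists matched on size and mean expression in 20 bins. Correlations across lines used 1 mean per line and 100000 permutations. Where a gap of over 2 log2 units separated at least 2 lines on each side, r was computed only within clusters of at least 6 lines.

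Groups, tests, lists, gene pairs and the rule for named genes were set before the data were examined. Named were up to 4 genes per list past the F test with the widest range between line means, the 20 genes with the largest SD of line means, the 25 genes with the widest gap between 1 line and its nearest neighbour (at most 2 per line, every array of the line beyond all others), the fixed line-gene pairs and gene pairs, and 10 genes in each direction for FarageX1 against Farage. BCL2, IRF4, MYC, ITGB2 and CD24 were chosen for the single SU-DHL-4 arrays after their values were seen, and so were MSH6 in Farage and OCI-Ly19 and the genes given for FarageX1 against NU-DHL-1 and for Farage against OCI-Ly19. The 2 array sets were recognised from the bioD control, with a threshold of 14.

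The procedure was tested on simulated data, drawn from normal distributions with the mean and within-line SD of each of 19775 genes and known differences added. Such values lack the correlation between genes and the non-normal spread of real arrays. The changed genes were drawn only from those with a mean of at least 4, so the recovery does not cover dimmer genes. The line with 1 array was given the same spread as the others, so that assumption was not tested. For a line with 2 arrays, 83% of differences of 2 log2 units and 99% of differences of 4 were recovered against the mean of the others, and for a line with 1 array 55% and 98%, with 0 false calls. The F test recovered 66% and 93% for a line with 2 arrays and 29% and 89% for a line with 1, with 2 and 5 false calls.

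Alternatives were quantile normalization, centring arrays on their median, filters at a mean of 4 or 6, the mean of all probe sets, eBayes without trend or with a robust prior, a replicate block, the 3' to 5' ratio of control probe sets as a covariate, only lines with more than 1 array, leaving out 1 array at a time, a plain test against 0, and camera with an estimated correlation or on ranks. Added later were the array set as a block, comparisons within an array set, a spread taken from SU-DHL-4 alone, leaving out FarageX1, and pairs of lines with 1 array per line (lowest replicate number). Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.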

Results

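Gene expression was profiled in 63 arrays of 40 untreated human non-Hodgkin lymphoma cell lines, which are cultures grown from lymphoid tumours and kept in the laboratory. Of the 40 lines, 20 had 1 array, 19 had 2 arrays and SU-DHL-4 had 5. The labels name the line and no lymphoma type, so each line was treated as its own group. Each array gave a log2 value for 54675 probe sets, from which 19775 named genes were taken. Array medians lay between 3.04 and 3.24 and upper quartiles between 6.07 and 7.11, the lowest being Ramos replicate 2 (6.07, against 6.56 in Ramos replicate 1). The number of arrays per line limits the precision. For the 20 lines with 1 array there was no replicate, and they were assumed to vary as the replicated lines did. The labels do not say whether replicates were separate cultures, so the p-values measure only the spread between these arrays, which may be technical. Each probe set has its own floor, the level it reads without signal, so a difference from a line at the floor is not a full fold change.

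The arrays also separated by a control transcript that is added at hybridization and does not come from the cells. This control, bioD, read 13.1 to 13.81 in 20 arrays (set A) and 14.34 to 15.25 in 43 arrays (set B), and the 3' minus 5' difference of the ACTB control probe sets was 0.66 to 1.21 in set A and 1.4 to 3.08 in set B. Set A held 19 of the single-array lines and SU-DHL-4 replicate 1. Set B held all other arrays, among them A4_Fukada, the remaining single-array line. Because SU-DHL-4 alone was in both sets, the comparisons were also made within a set.

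Arrays of the same line resembled each other closely. The 19 lines with 2 arrays had a median Pearson correlation across genes of 0.998 (0.988 in Ramos, 0.997 to 0.999 in the other 18), against 0.922 (0.837 to 0.994) for 1924 pairs of arrays of different lines. Genes are not independent replicates, so no p-value is attached to these correlations. For all 43 arrays with a partner, the nearest other array belonged to the same line. Over genes with a mean of at least 6 this held for 42 arrays. There the median correlations were 0.995 in 2-array lines and 0.719 between different lines. Over the 2000 most variable genes they were 0.995 and 0.49, so the correlation between lines depends on the genes used. Between the arrays of a 2-array line a median of 6 genes lay at least 2 log2 units apart (2 to 36 without Ramos, which had 190). SU-DHL-4 differed from this, since replicates 2 and 3 were 6 genes apart and replicates 4 and 5 were 3 genes apart, while 642 to 663 genes separated an array of the former pair from one of the latter and 718 to 878 genes separated replicate 1 from the others. BCL2, an inhibitor of apoptosis, read 3.13, 3.69, 3.64, 13.1 and 13.31 in SU-DHL-4 replicates 1 to 5. IRF4, a transcription factor of late B-cell differentiation, read 2.09, 5.25, 5.64, 9.22 and 8.92. The integrin chain ITGB2 read 9.48, 7.48, 7.6, 4.07 and 3.64, and MYC read 13.45, 10.05, 9.81, 12.24 and 12.25.

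**Figure D1:**
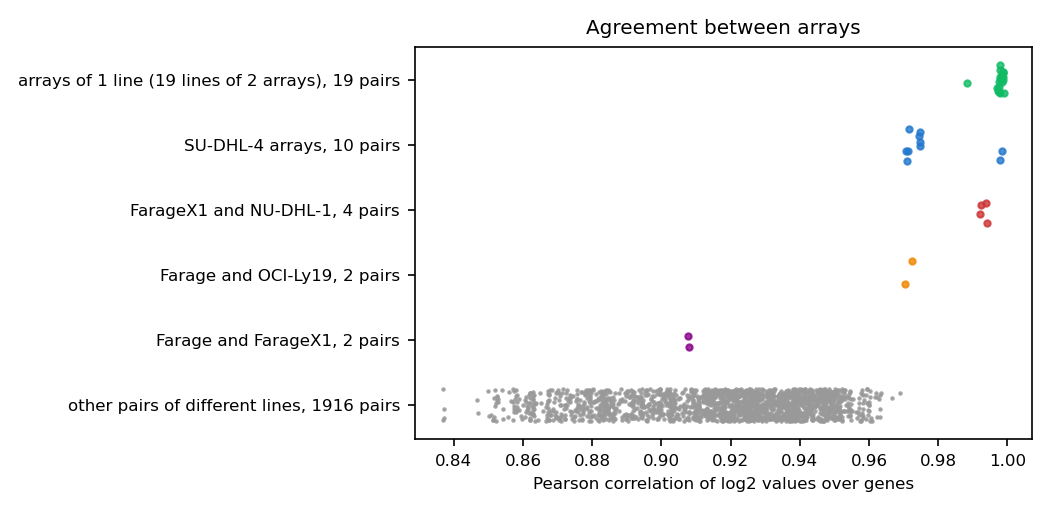
Pearson correlation of log2 values over genes (x axis) for pairs of arrays, 1 point per pair, grouped by the lines the arrays belong to (y axis). Arrays of 2-array lines sit at 0.988 or more, FarageX1 and NU-DHL-1 at 0.992 to 0.994, and Farage and OCI-Ly19 at 0.97 to 0.972.

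**Figure D2:**
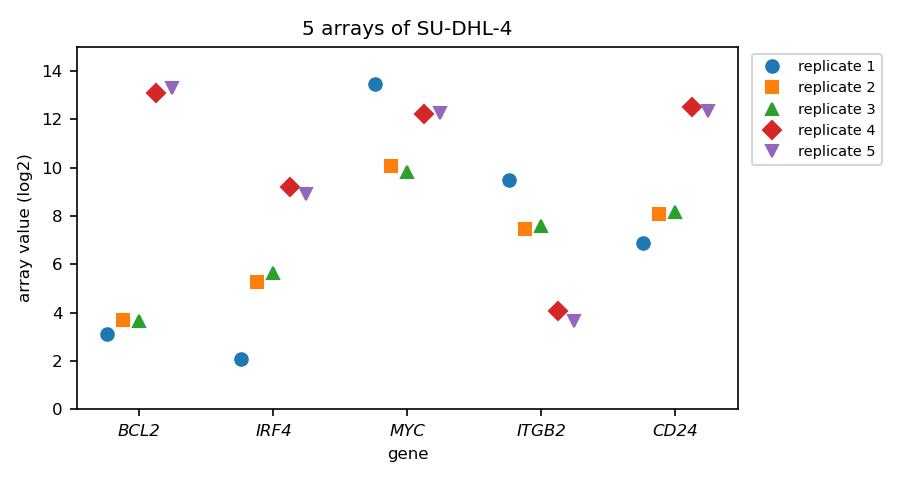
Values (log2, y axis) of 5 genes in each of the 5 SU-DHL-4 arrays, 1 symbol per array and no error bars; the genes were chosen after their values were seen. BCL2 lies between 3.13 and 3.69 in replicates 1 to 3 and at 13.1 and 13.31 in replicates 4 and 5, and CD24 at 6.86 to 8.15 and at 12.51 and 12.35.

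The comparison of all lines asked which genes differ among them. IGHM, the mu heavy chain, had the largest SD of line means (5.61 over 40 lines, pooled within-line SD 0.63). It was at 8 or more in 19 lines and below 4 in 20, from 15.73 in GRANTA-519 to 3.5 in Karpas-422. HLA-DRA, the alpha chain of the HLA-DR molecule, reached 15.01 in Pfeiffer and lay at 2.18 in SCC-3, with 31 lines at 8 or more and 8 below 4. RGS13, a regulator of chemokine-receptor signalling in germinal-centre cells, ranged from 14.61 in DB to 3.48 in NU-DHL-1, and 20 lines were at 8 or more. JCHAIN, which joins immunoglobulin polymers, ranged from 15.4 in Pfeiffer to 3.06 in NU-DHL-1.

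Also among the 20 most variable genes, the intermediate filament gene VIM ran from 15.2 in SR to 2.62 in DB, the lectin gene LGALS1 from 15.42 in SR to 2.23 in U-698-M, and the hyaluronan receptor CD44 from 13.64 in REC-1 to 2.43 in WSU-DLCL2. GLUL, glutamine synthetase, was at 14.96 in SCC-3 and 2.4 in SU-DHL-6. The AKT coactivators TCL1A and TCL1B peaked in TK (15.14) and Toledo (14), TCL1A being at 8 or more in 27 lines and TCL1B in 10. The chemokine receptor CXCR4 was at 15.73 in SU-DHL-8 and 2.8 in BJAB. The T-cell kinase LCK, at 13.33 in U-698-M and 2.4 in SCC-3, was at 8 or more in 24 lines. The remaining members were YBX3, UCHL1, MARCKS, IGLL1, HLA-DQA1, GTSF1, NAPSB and BCL2A1, each with an SD of line means between 4.21 and 4.83.

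By limma's moderated F test 15088 of 19775 genes (76.3%) differed among lines, and 11200 of them also spanned at least 2 log2 units between the highest and the lowest line mean. Within set B the counts were 13128 and 9642, and within set A, with the spread taken from set B, 11907 and 8558. The F count was 9572 among genes with a mean of at least 4 (genes differing among cell lines). It was 3918 when the spread came from the 3 separate kinds of SU-DHL-4 array alone, an alternative under which YBX3, UCHL1, MARCKS, IGLL1, CXCR4 and BCL2A1 were among the genes no longer past the threshold.

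Taken in pairs, the lines differed in a median of 1809.5 genes over 780 pairs (61 to 3521), by a limma test against a difference of 1 log2 unit. The closest pair was FarageX1 and NU-DHL-1, with 61 genes. Next came DoHH2 and SU-DHL-4 with 512, Farage and OCI-Ly19 with 531, and DoHH2 and WSU-DLCL2 with 643. The median was 1356 within set A (171 pairs), 2060.5 within set B (210 pairs) and 1889 across sets (399 pairs). Set A has 1 array per line and set B mostly 2, and with 1 array per line throughout the medians were 1341.5, 1665.5 and 1662.5. Under a plain test against 0 (genes differing between 2 cell lines) the median over pairs was 5212.5, it was 1186.5 among genes with a mean of at least 6, and it was 446 with the spread of SU-DHL-4 alone.

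Each line was next set against the equally weighted mean of the other 39 to find what sets it apart. SCC-3 carried S100A9, a calcium-binding protein of myeloid cells, at 14.45 ± 0.05 (SD, n = 2), with no other line mean above 2.83, and the synaptic vesicle gene SYNPR at 13.81 ± 0.18. A3_Kawakami expressed MAGEA4, a cancer-testis antigen, at 14.56 ± 0.1 (n = 2), the next line being A4_Fukada at 4.76, and DSCR8 at 11.56 ± 0.03. Jeko1 had the dipeptidase gene DPEP3 at 12.64 and the alpha heavy chain IGHA1 at 11.62, REC-1 the collagenase MMP1 at 11.48, Pfeiffer the serotonin receptor HTR2B at 11.07 and the chemokine CX3CL1 at 9.89, and HT the somatostatin receptor SSTR1 at 11.06 and C11orf97 at 11.69, each from 1 array. Some lines had low levels of genes that were high in all others. HPRT1, a purine salvage enzyme often used as a reference gene, was at 2.02 ± 0.01 (n = 2) in U-698-M and at 11.26 or more in every other line. TMEM123 was at 2.22 in BJAB (11.86 or more elsewhere), the RNA-binding protein gene QKI at 2.39 in Karpas-422 (10.66 or more elsewhere), and HACD3, of very-long-chain fatty acid synthesis, at 2.26 ± 0.03 in RC-K8 (9.99 or more elsewhere).

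The other genes with the widest gap to the nearest line were all higher in their line. They were C6orf58 in RC-K8 (12.71), MAL in KARPAS-1106P (11.94), ASZ1 in SU-DHL-6 (12.3), CCN4 in A4_Fukada (10.91), PRR16 in BJAB (11.33), PLVAP in GRANTA-519 (10.57), PLPP2 in U-698-M (9.56), MYBPH in Karpas-422 (10.3), CNRIP1 in WSU-NHL (10.38) and MS4A6A in NU-DUL-1 (10.87). In these 10 genes the nearest other line mean was between 1.58 and 3.41. The adjusted p of the 25 genes was at most 1.73e-22, the value for IGHA1 in Jeko1, and at most 2.3e-24 within the array set. These genes were picked for their gap from the same values, so the p-values are no separate evidence for it. For the genes higher in their line, the pooled spread came mostly from arrays at or near the floor. These p-values therefore do not measure the spread of an expressed level, which was not measured at all in lines without a replicate. IGHA1 and HPRT1 each had a second probe set that did not follow the one used (r of -0.07 and 0.19 over line means).

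A line differed from the mean of the others in a median of 1207.5 genes, 658.5 higher and 558 lower, from 608 in DoHH2 to 2588 in SCC-3. More arrays give more calls, and the median was 1492.5 for lines with more than 1 array and 987.5 for lines with 1. The number of arrays goes with the array set, so this gap cannot be put down to the number of arrays alone. A3_Kawakami had 2315, OCI-Ly19 2255 and SU-DHL-1 2152, but with either array left out 1919 to 1937, 1652 to 1759 and 1793 to 1803, against 2208 to 2216 in SCC-3 and 1957 in SR with its single array. Against the lines of the same array set the median was 1347, and a median of 86.55% (76.5 to 95.4) of a line's calls were also made there. Every line had genes that lay beyond every array of all other lines, 6945 higher and 3572 lower in all, from 24 in SU-DHL-4 to 757 in SCC-3. The median was 6094.5 under a plain test against 0, 782 among genes with a mean of at least 6 and 201.5 with the spread of SU-DHL-4 alone (genes of one line against the mean of the other lines). Ramos had 1559 genes, 27.1% of them higher, but 1020 without replicate 2, and after quantile normalization 49% of its calls were higher.

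The next comparison took 17 line-gene pairs that textbook knowledge ties to these established lines. No direction was fixed for a pair, so a pass shows a difference either way and not an expected one. The receptor tyrosine kinase gene ALK, which a translocation activates in anaplastic large cell lymphoma, was at 13.4 ± 0.06 (SD, n = 2) in SU-DHL-1 and 12.98 in SR, against a mean of 3.76 and 3.78 over the respective other lines. These lines were the highest. The SD over the respective other lines was 1.96 and 2.02, so ALK is not shown to be restricted to SU-DHL-1 and SR. TNFRSF8, which encodes CD30, was at 10.24 ± 0.06 in SU-DHL-1 and 11.48 in SR. PAX5, the factor that holds B-cell identity, was lower in both, at 3.34 ± 0.87 and 4.71 against other-line means of 11.43 and 11.4. The cyclin gene CCND1, activated by translocation in mantle cell lymphoma, was at 14.31 in Jeko1, 14.09 in GRANTA-519 and 14.4 in REC-1, against an other-line mean of at most 3.47. SOX11, a transcription factor of mantle cell lymphoma, was at 11.21 in Jeko1, although RI_1 had the highest level (13.06).

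KARPAS-1106P, a line of mediastinal B-cell lymphoma, had MAL, a membrane raft protein gene, at 11.94 ± 0.06 (n = 2) and the secreted amino acid oxidase gene IL4I1 at 9.05 ± 0.43, below the 11.86 of OCI-Ly19. CDKN2A, a cell-cycle inhibitor often deleted in lymphoma, was lower there, at 5.9 ± 0.69 against 9.69. TCL1A was higher in the Burkitt line Ramos, at 14.42 ± 0.15 against 9.64. Of the 17 pairs 14 passed, 11 higher and 3 lower, the largest adjusted p among them being 5.57e-10 for IL4I1, and these 14 passed within their array set (adjusted p at most 3.25e-10). BCL2 was at 3.4 in Ramos (difference -4.23, SE 1.54, adjusted p = 0.24) and 3.49 in DoHH2 (difference -4.14, SE 2.15, adjusted p = 1). IRF4 in RI_1 was at 11.05 (difference 2.91, SE 1.22, adjusted p = 0.725, 0.00599 within its array set). BCL2 and IRF4 have large standard errors because their within-line SD, 2.23 and 1.26, includes the spread among the SU-DHL-4 arrays. The pairs in SR, Jeko1, GRANTA-519, REC-1, DoHH2 and RI_1 rest on 1 array each. CCND1 was below 4 in 35 lines and at 8 or more only in 3 lines without a replicate. Its p-values therefore do not measure the spread of an expressed level.

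BCL2 lies on chromosome 18 from 63123346 to 63320090 and CCND1 on chromosome 11 from 69641156 to 69654474, while ALK lies on chromosome 2 from 29192774 to 29921586 (build GRCh38.p14). The other BCL2 probe sets did not all follow the brightest, with r of 0.74, 0.19 and 0.18 over line means. Karpas-422 was lowest by the brightest BCL2 probe set (2.95), whereas another of its BCL2 probe sets read 6.29 there. With the spread of SU-DHL-4 alone, IL4I1 in KARPAS-1106P (adjusted p = 0.254) and TCL1A in Ramos (adjusted p = 0.307) no longer passed. With the array set as a block, BCL2 in Ramos (adjusted p = 0.0258) and IRF4 in RI_1 (adjusted p = 0.000509) passed. Only SU-DHL-4 was in both sets, so this block is estimated from its replicate 1 against replicates 2 to 5. There BCL2 read 3.13 against 3.64 to 13.31, and IRF4 2.09 against 5.25 to 9.22. The block thus carries the spread among the SU-DHL-4 arrays, and these calls decide nothing.

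**Figure D3:**
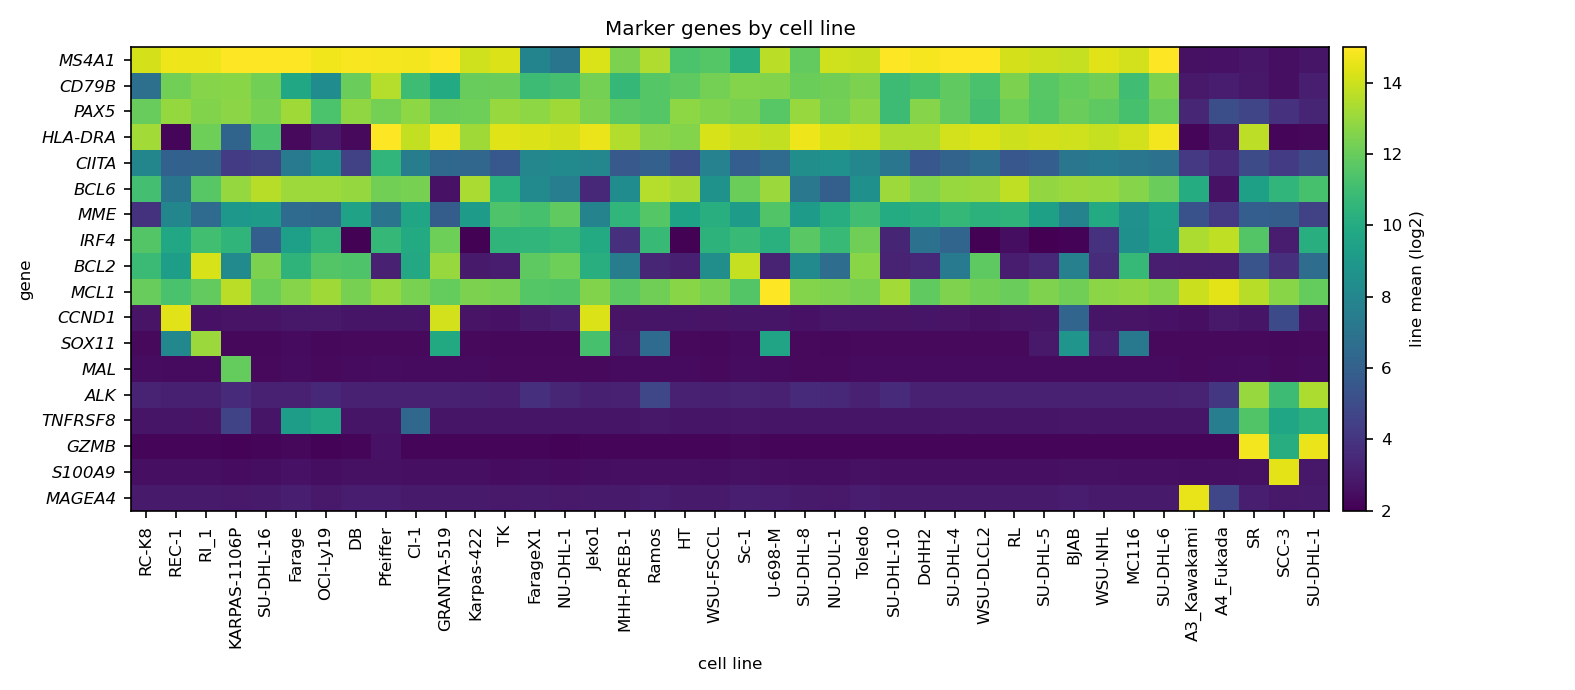
Line mean (log2, colour) of 18 genes (y axis) in 40 cell lines (x axis), the lines being ordered by similarity of their gene-list differences. ALK is brightest in SU-DHL-1 (13.4) and SR (12.98), CCND1 in Jeko1, GRANTA-519 and REC-1, MAL in KARPAS-1106P (11.94) and S100A9 in SCC-3 (14.45).

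Gene groups were followed across lines with 25 lists. B-cell surface antigens were called lower in 9 lines (5 with an estimated correlation), B-cell transcription factors and receptor signalling genes in 8 (6) and immunoglobulin genes in 6 (5). They were called higher in 23 (11), 26 (18) and 6 (4) lines, against a mean that includes the lines where they are low. In each of these lists the mean difference was lowest in SU-DHL-1, SCC-3 and SR, and A3_Kawakami and A4_Fukada followed in surface antigens (-4.15 and -3.87) and transcription factors (-3.48 and -4.62). B-cell surface antigens were lower by a mean difference of -4.54 in SCC-3, -4.5 in SU-DHL-1 and -4.46 in SR, with 16, 16 and 15 of 21 measured members lower and none higher (17, 16 and 17 lower adjusted over the list alone; adjusted p of the shifts at most 8.58e-10). MS4A1, which encodes CD20, ran from 15.22 in SU-DHL-10 to 2.52 in SCC-3, the B-cell receptor chain CD79A from 14.02 in SU-DHL-6 to 2.62 in SU-DHL-1, the tetraspanin CD37 from 13.6 in RI_1 to 1.73 in SCC-3 and FCRLA from 14.89 in SU-DHL-16 to 2.98 in SCC-3. B-cell transcription factors and receptor signalling genes were lower in the same lines, by -5.36 in SU-DHL-1 (16 of 19 lower), -5 in SCC-3 (15 lower) and -4.65 in SR (14 lower). Among them POU2AF1, a coactivator of immunoglobulin genes, was at 2.53 in SR, the adaptor BLNK at 2.18 in SU-DHL-1, and SPIB and VPREB3 at 2.18 and 1.97 in SCC-3. Immunoglobulin genes were lower in SCC-3 (-4.18), SU-DHL-1 (-4.03) and SR (-3.88), and higher in Jeko1 by 3.94 (6 of 9 members) and in WSU-FSCCL by 3.2 (6 members).

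The anaplastic large cell lymphoma list went the other way in these 3 lines. It was higher by 7.7 in SR (13 of 14 members), 6.98 in SU-DHL-1 (12 members) and 6.85 in SCC-3 (13 members). The granule proteases and pore protein of cytotoxic cells, GZMB and PRF1, were at 14.77 and 15.47 in SR, and TIMP1 and SERPINA1, a metalloprotease inhibitor and a serine protease inhibitor, at 15.14 and 15.21 in SCC-3. This list was called lower in 32 lines, of which 27 held with an estimated correlation, but the mean they are set against includes these 3 lines, so a line with members at the floor is lower by construction (NU-DHL-1 by -1.17, with 3 of 14 members lower, and HT by -1.13, with 1 lower, or 3 adjusted over the list alone). Myeloid markers were higher in SCC-3 by 4.14 (7 of 11 members), where CD14, a lipopolysaccharide coreceptor, was at 10.11, while FCER1G and CD300A were highest in SU-DHL-1 (12.25 and 10.52). The list was called lower in 32 other lines, but in none of these with an estimated correlation and with no member lower in any of them. T-cell and NK-cell markers were called higher in no line and lower in 27, of which 7 held with an estimated correlation, but at most 2 of 21 members were lower in any of them, and members at the floor are again lower by construction (CD3D was below 4 in 36 lines and NKG7 in 35). CD3D was highest in SR (12.57) and NKG7 in SCC-3 (13.09), and the T-cell coreceptor CD8A was at 12.96 in Pfeiffer and at 8 or more in no other line.

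Antigen-presentation genes varied beyond these 3 lines. MHC class II genes were lower by -6.52 in SU-DHL-1 (11 of 12 members), -5.46 in A3_Kawakami (11 members) and -5.35 in REC-1 (9 members), and higher by 3.51 in Pfeiffer (11 members) and 3.1 in SU-DHL-6 (11 members). The invariant chain CD74 ran from 15.28 in Pfeiffer to 2.68 in SCC-3, and HLA-DPA1 and HLA-DPB1 from 14.83 and 14.48 in Pfeiffer to 2.13 and 2.24 in REC-1. MHC class I and peptide loading genes were higher in GRANTA-519 by 1.53 (3 of 13 members). In DB their mean difference was -2.65 (5 members lower, adjusted p = 2.1e-06). The DB call was lost at adjusted p = 0.0599 with an estimated correlation. HLA-B, HLA-C and HLA-E, which present peptides to cytotoxic T cells, were at 4.81, 4.61 and 4.87 in DB, and their regulator NLRC5 ranged from 10.29 in NU-DHL-1 to 1.96 in RL.

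Germinal-centre genes were higher in KARPAS-1106P by 2.96 (13 of 16 members), in DoHH2 by 2.8 (10 members) and in RL by 2.61 (12 members), and lower in A3_Kawakami by -4.15 (14 members), SCC-3 by -4.14 (14 members) and A4_Fukada by -3.75 (13 members). BCL6, the repressor that sets the germinal-centre state, was at 13.75 in RL and 2.64 in A4_Fukada, LMO2 at 14.68 in Farage and 3.42 in TK, and IRAG2 at 14.9 in RL and 3.07 in SCC-3. Plasma-cell genes were higher in A4_Fukada by 3.26 (10 of 11 members), A3_Kawakami by 3.13 (8 members) and GRANTA-519 by 2.13 (5 members). Among them MZB1, a chaperone of antibody assembly, was at 12.48 in A4_Fukada, the elongation factor ELL2 at 13.43 in A3_Kawakami, and TNFRSF17, a survival receptor of plasma cells, at 14.72 in Pfeiffer. Activated-B-cell-like genes were higher in RI_1 by 2.7 (10 of 17 members), where FOXP1 was at 13.53, and lower in SU-DHL-10 by -2.42 (10 members). IRF4 was at 13.75 in A4_Fukada and 1.88 in SU-DHL-5, and the kinase PIM1 at 11.5 in U-698-M and 1.14 in DB.

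Signalling lists also singled out particular lines. NF-kB target genes were higher in RC-K8 by 3.49 (12 of 18 members), Farage by 3.18 (14 members) and OCI-Ly19 by 3.15 (13 members), and lower in TK by -2.28 (11 members), MHH-PREB-1 by -1.97 (9 members) and DB by -1.88 (10 members). BCL2A1, an anti-apoptotic NF-kB target, was at 14.34 in OCI-Ly19 and 2.8 in A4_Fukada, and the chemokine CCL22 at 12.22 in RC-K8. The JAK-STAT and mediastinal B-cell lymphoma list was higher in KARPAS-1106P by 3.37 (12 of 16 members), where the interleukin receptor gene IL4R was at 12.86, whereas the chemokine CCL17 and the NF-kB subunit REL were highest in Pfeiffer (14.61 and 14.27). This list was called lower in 20 lines, 10 of them with an estimated correlation. Interferon-stimulated genes were higher in Karpas-422 by 3.85 (14 of 19 members), SR by 2.97 (13 members) and CI-1 by 1.91 (9 members). They were called lower in 15 lines, 7 of them with an estimated correlation. ISG15 and MX1, antiviral effectors, were at 14.29 and 12.57 in Karpas-422. IFIT3 was at 11.13 in GRANTA-519 and MX2 at 11.06 in TK.

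Hypoxia and glycolysis genes were higher in OCI-Ly19 by 2.3 (7 of 15 members), with BNIP3, a mitochondrial protein of the hypoxia response, at 14.03 and the aldolase gene ALDOC at 13.62. They were also higher in A3_Kawakami by 1.73 (7 members). Migration and adhesion receptors were higher in A4_Fukada by 1.95 (8 of 15 members) and GRANTA-519 by 1.84 (5 members), and lower in RC-K8 by -2.06 (7 members). The integrin chain ITGA4 and the selectin ligand SELPLG peaked in A4_Fukada (12.72 and 11.88), and the adhesion molecule CD58 was at 13.09 in Farage and 2.33 in KARPAS-1106P. Cancer-testis antigens were higher in A3_Kawakami by 3.2 (4 of 10 members) and A4_Fukada by 2.21 (5 members), with MAGEA1 at 10.53 in A3_Kawakami and MAGEC1 at 9.87 in A4_Fukada. PRAME was highest in Jeko1 (11.28). Epithelial markers had a mean difference of 2.29 in A4_Fukada (5 of 9 members higher, adjusted p = 3.88e-06). That call was lost at adjusted p = 0.0568 with an estimated correlation. KRT18 and KRT8 were highest in A3_Kawakami (10.55 and 7.49) and EPCAM in Pfeiffer (14.21).

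G1 cell-cycle regulators were lower in DB by -0.75 (5 of 19 members lower, 1 higher, adjusted p = 0.00445). The kinase CDK6 was at 14.19 in SU-DHL-1 and 2.45 in Jeko1, and the retinoblastoma gene RB1 at 14.14 in KARPAS-1106P and 3.33 in U-698-M. BCL2 family and apoptosis genes were called in 6 lines, fibroblast and stromal markers in 15, proliferation genes in 5, nucleolar and MYC-responsive genes in 6, drug efflux transporters in 4 and housekeeping genes in 2, and with an estimated correlation in none. The single members still ranged widely. FAS, a death receptor, was at 13.34 in KARPAS-1106P and 2.72 in DB, BIK at 12.84 in Farage, PMAIP1 at 14.5 in RI_1 and 3.56 in A3_Kawakami, the collagen gene COL6A3 at 13.77 in A3_Kawakami, the proteoglycan gene DCN at 14.26 in Karpas-422, and the drug pump ABCB1 at 10.66 in REC-1.

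With a preset inter-gene correlation of 0.01, limma's camera called 458 of 1000 list-line combinations, 184 up and 274 down. With an estimated correlation 198 held, all in the same direction. Among the shifts given with a mean difference here, all held except those followed by an adjusted p above 0.05. Within the array sets the shifts of a line given here with a mean difference were all called, and 431 were called in all, of which 382 were called both ways in the same direction. In 11 calls the mean of a list and its test differed in sign, and in 1 the median did. With only genes of a mean of at least 6, 1 of 14 members of the anaplastic large cell lymphoma list was left, so that filter decides nothing for SR, SU-DHL-1 and SCC-3. The same filter left 5 of 19 interferon-stimulated genes, 6 of 16 JAK-STAT genes and 5 of 9 immunoglobulin genes, and these lists were then not called in Karpas-422 (adjusted p = 0.0624), KARPAS-1106P (0.053) and WSU-FSCCL (0.15). Camera on ranks did not call cancer-testis antigens in A3_Kawakami (adjusted p = 0.0736), and G1 cell-cycle regulators in DB were not called among genes with a mean of at least 4 (14 of 19 members left, adjusted p = 0.0931).

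In spread among lines, 20 of the 25 lists lay at or above the 95th percentile of 10000 random lists matched on size and expression. Immunoglobulin genes had a median SD of line means of 4.02, against 0.7 for random lists, MHC class II genes 3.16 against 0.74 and B-cell surface antigens 3.14 against 0.75. The lists below were fibroblast and stromal markers (percentile 51.2), epithelial markers (77.7), proliferation genes (56.3), nucleolar and MYC-responsive genes (64.9) and housekeeping genes (0.3). Proliferation genes had a median SD of 0.56 and housekeeping genes 0.38. The proliferation genes PLK1 and RRM2 ranged from 10.05 in WSU-NHL to 5.37 in SR and from 14.47 in SU-DHL-1 to 10.89 in HT, CAD of the nucleolar and MYC-responsive list from 11.79 in U-698-M to 8.05 in RI_1, and the housekeeping gene PGK1 from 15.49 in A3_Kawakami to 13.39 in SU-DHL-8. All measured members passed the F test in 16 of the lists. The exceptions were T-cell and NK-cell markers (17 of 21 over all genes, 17 adjusted over the list alone), myeloid markers (10 of 11 and 10), fibroblast and stromal markers (8 of 11 and 8), epithelial markers (8 of 9 and 8), interferon-stimulated genes (18 of 19 and 19), G1 cell-cycle regulators (18 of 19 and 18), migration and adhesion receptors (14 of 15 and 14), drug efflux transporters (8 of 10 and 8) and cancer-testis antigens (8 of 10 and 8). The percentile of the hypoxia and glycolysis list fell to 88.6 with the mean of all probe sets (hypoxia and glycolysis genes spread).

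**Figure D4:**
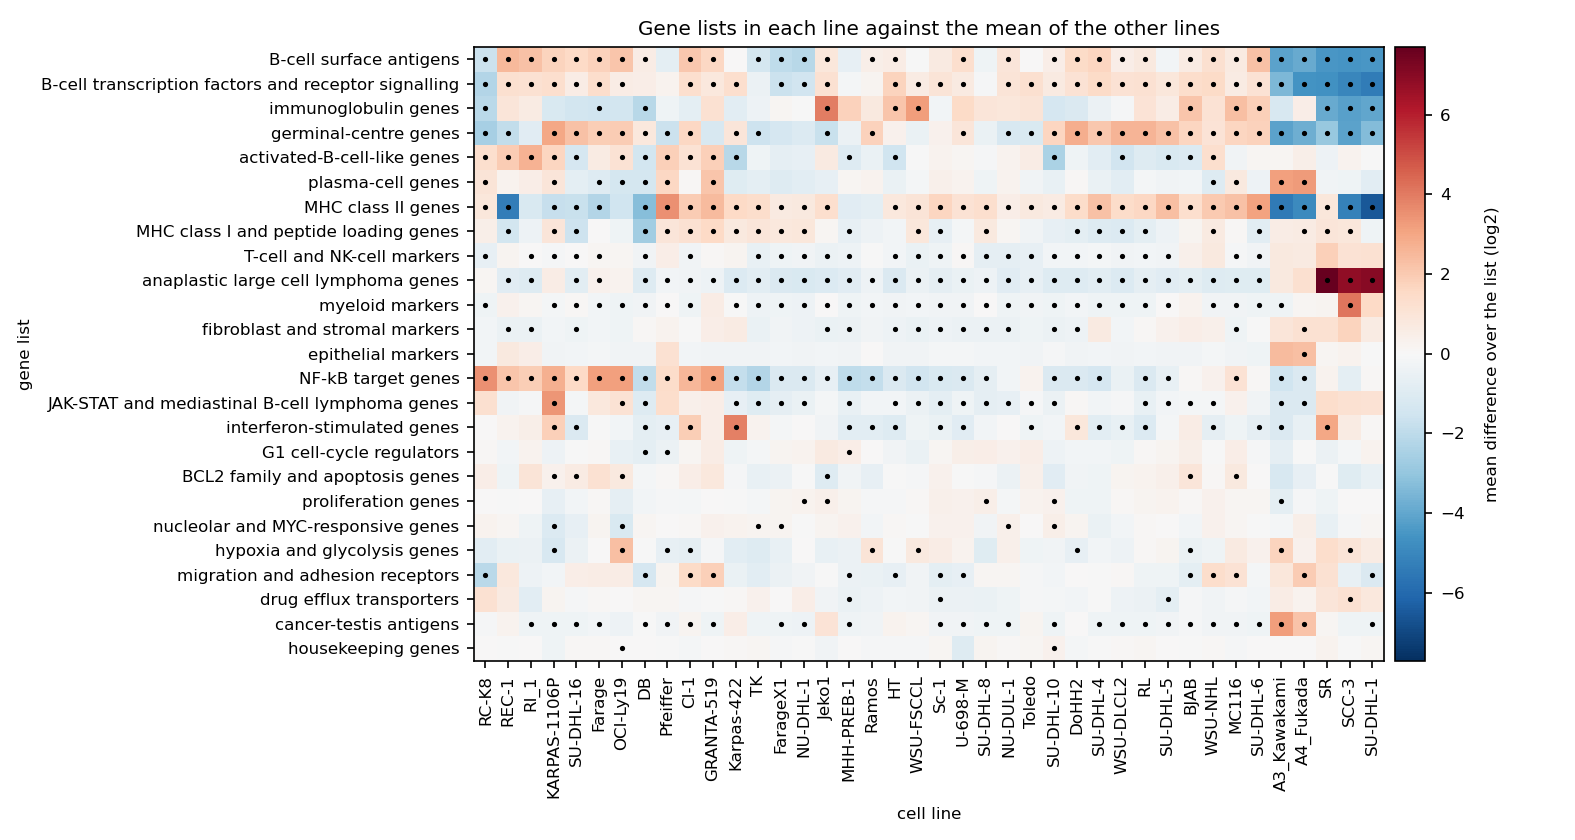
Mean difference (log2, colour) of 25 gene lists (y axis) in each of 40 cell lines (x axis) from the mean of the other lines; a dot marks an adjusted camera p under 0.05 with the preset correlation. SCC-3, SU-DHL-1 and SR are blue for the B-cell lists and red for the anaplastic large cell lymphoma list (6.85, 6.98 and 7.7).

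FarageX1 was compared with Farage because the names share a stem. The labels do not say how they are related. FarageX1 lay closest to NU-DHL-1 (61 genes), so whether its arrays hold the cells their label names is open, as taken up below. FarageX1 had HLA-DRA at 14.29 against 2.34 in Farage, the lambda light chain gene IGLC1 at 14.91 against 3.14, the surrogate light chain gene IGLL1 at 14.55 against 2.99 and the tetraspanin CD9 at 14.74 against 3.31. DNTT, the template-independent DNA polymerase of early lymphocytes, was at 14.36 against 3.7, and the mismatch repair gene MSH6 at 12.78 against 1.58. SOCS2, AKAP12, IGLV1-44 and CHST15 were also among the 10 with the largest gain, by 10.32 to 11.02. Farage had the higher level of BASP1 (13.94 against 1.72), BCL2A1 (14.28 against 2.83), HOPX (13.62 against 2.33) and the cytokine IL32 (12.82 against 2.02). NAPSB, FEZ1, ANXA5, LGALS3, SEL1L3 and LCK differed by -11.04 to -10.2. FarageX1 had 2 arrays and Farage 1, and the largest adjusted p of these 20 genes was 8.01e-10, for IGLL1.

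In FarageX1 the NF-kB target genes were lower by a mean of -4.17 (12 of 18 members lower, none higher), B-cell surface antigens by -3.63 (13 of 21 lower, 1 higher), germinal-centre genes by -3.11 (10 of 16 lower, 2 higher) and B-cell transcription factors and receptor signalling genes by -2.92 (10 of 19 lower). MHC class II genes were higher by 2.82 (7 of 12 higher, 2 lower). Each of these 5 shifts held with an estimated correlation (adjusted p of 0.015 to 0.0391). MHC class I and peptide loading genes had a mean difference of 0.75 (adjusted p = 0.000691). That call was lost at adjusted p = 0.193 with an estimated correlation, and the other 19 lists were not called.

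In all 1987 genes differed, 718 higher and 1269 lower in FarageX1. By this count the pair ranked at 478 of 780 from the closest, with a correlation of 0.908. Farage is in set A and FarageX1 in set B, so no value within a set can be given. The share higher was 36.1%, and 48.3% after quantile normalization. The count was 8066 under a plain test against 0 and 506 with the spread of SU-DHL-4 alone (FarageX1 against Farage). Under the latter IGLL1, IGLV1-44, BCL2A1 and LCK did not pass.

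**Figure D5:**
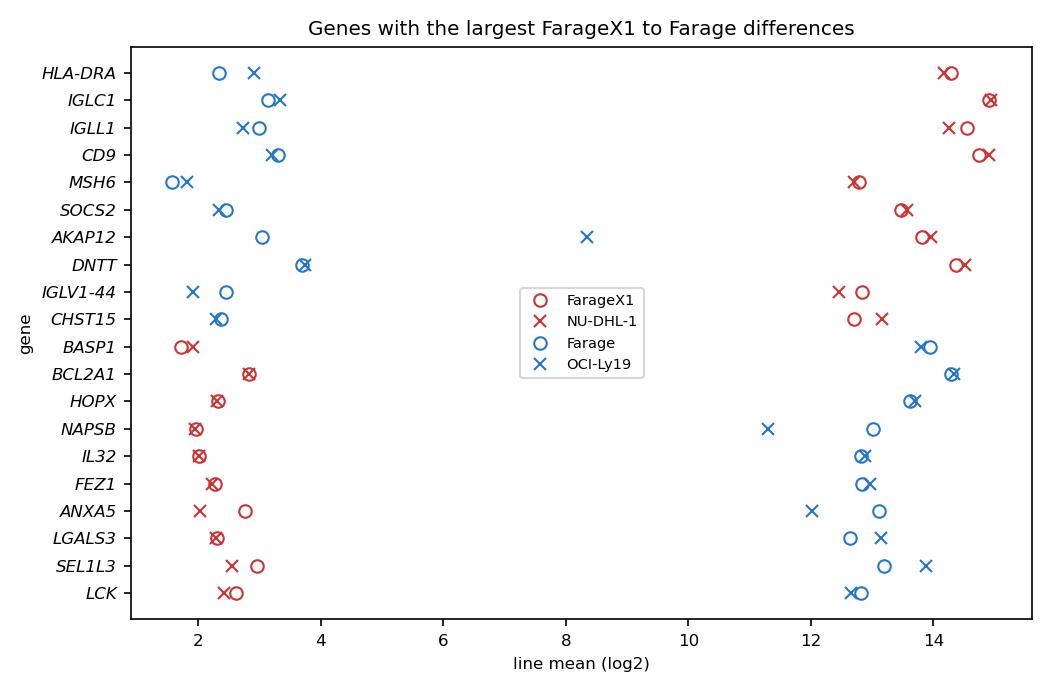
Line mean (log2, x axis) of the 20 genes (y axis) with the largest differences between FarageX1 (red circles) and Farage (blue circles), with NU-DHL-1 (red crosses) and OCI-Ly19 (blue crosses) beside them. AKAP12 is at 8.35 in OCI-Ly19 and 3.04 in Farage, NAPSB at 11.3 and 13.01, and ANXA5 at 12.01 and 13.11.

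Gene pairs fixed before the data were examined were followed across lines, with 1 mean per line and two-sided permutation tests. CIITA, the master regulator of MHC class II transcription, rose with HLA-DRA over the 31 lines with HLA-DRA at 11.28 to 15.01 (Pearson r = 0.58, permutation p = 0.00087, adjusted 0.0148; Spearman rho = 0.54, permutation p = 0.00197, adjusted 0.0193). Without Pfeiffer and SU-DHL-16 r was 0.41, and it was 0.59 in set A (17 lines) and 0.58 in set B (15 lines). Over the 8 lines with HLA-DRA at 2.18 to 2.91 r was 0.41 (permutation p = 0.322), and -0.56 without OCI-Ly19 and Farage.

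BCL2 and MCL1, both inhibitors of apoptosis, were inversely related over 40 lines (r = -0.46, permutation p = 0.00192, adjusted 0.0163; rho = -0.47, permutation p = 0.00227, adjusted 0.0193). Without RI_1 and Sc-1 r was -0.41, and it was -0.41 in set A and -0.5 in set B. The BCL2 mean of SU-DHL-4 used here, 7.37, averages arrays at 3.13 to 3.69 with arrays at 13.1 and 13.31, a level that no array had. The relation also rests on the brightest BCL2 probe set, which the others followed with r of 0.74, 0.19 and 0.18. IRF4 and PRDM1, which drive plasma-cell differentiation, gave r = 0.53 (permutation p = 0.00616, adjusted 0.0349) but rho = 0.24 (permutation p = 0.213, adjusted 0.604) over 29 lines with IRF4 at 5.86 or more. There r was 0.62 without SU-DHL-16 and SU-DHL-4, 0.34 in set A and 0.6 in set B.

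IRF4 and BCL6, mutually antagonistic regulators, had r = -0.46 over 26 lines with both genes high (permutation p = 0.0159, adjusted 0.0674; rho = -0.5, permutation p = 0.0104, adjusted 0.0588), which did not pass; r was -0.37 without SU-DHL-16 and SU-DHL-4 and -0.45 in each array set. MYC and NCL, a nucleolar gene that MYC induces, had r = 0.28 (permutation p = 0.0774, adjusted 0.146; 0.18 in set A and 0.61 in set B), and the proliferation genes MKI67 and CCNB1 had r = -0.1 (permutation p = 0.527, adjusted 0.689; 0 in set A and 0.06 in set B). In all 17 relations were computed over 12 measured pairs, 9 of which had separate clusters of lines and no pooled r; 3 passed by r and 2 by rho. Using the mean of all probe sets, the adjusted p was 0.0594 for the correlation of CIITA and HLA-DRA, lines with higher HLA-DRA, and 0.0854 for the correlation of BCL2 and MCL1, all lines. Over only lines with more than 1 array none of 13 relations passed.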

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

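The tests of a shared array set for FarageX1 and NU-DHL-1 and of the array sets as a source of the counts were chosen after those results were seen, and so were the comparison with 1 array per line and the SE given for Farage and OCI-Ly19; the others in this part were set down before.

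Values of the 5 SU-DHL-4 arrays were searched for an array far from the rest, 41 values in all, and 6 met the criterion, each time for replicate 1, the only SU-DHL-4 array in set A. Chance would mark about 1 in 20 groups of 5 independent arrays, but these 5 are not independent. Replicates 2 and 3 were 6 genes apart, and replicates 4 and 5 were 3 genes apart. Within such pairs no array can lie alone, so the criterion could hardly mark any array but replicate 1. The 6 values are not independent either, and bioD also defined the array sets. These marks therefore do not single out the array set. The mean of the B-cell surface antigens was 8.52 in replicate 1 against 9.35 to 9.5 in the other 4 arrays. The mean of the activated-B-cell-like genes was 6.11 against 6.93 to 7.16. BCL2 family and apoptosis genes averaged 7.52 against 8.04 to 8.17. Myeloid markers averaged 2.62 against 2.58 to 2.59. The array median was 3.1 against 3.08 in each of the other 4, and the bioD control was 13.13 against 14.58 to 14.79.

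FarageX1 lay closer to NU-DHL-1 than any other pair of lines, with 61 genes past the test (9 higher, 52 lower in FarageX1) and 23 genes in which both lay at least 2 log2 units beyond all other lines. An effect of the shared array set is excluded as the whole cause, since the lowest correlation of the pair (0.992) exceeded the highest of FarageX1 with any other line of the set (0.959) by 0.033. The 17 identity genes, which tend to be fully on or off in a line, differed by a mean of 0.14 log2 units, where arrays of a single line differed by up to 0.55, so these arrays may hold the cells of 1 line through a mixed-up label or culture, although 93 to 132 genes lay at least 2 log2 units apart (r of 0.992 to 0.994), against 2 to 36 genes (r of 0.997 to 0.999) in 2-array lines other than Ramos, which had 190 (r of 0.988). In the identity genes the closest other pair of different lines differed by 0.47, also under 0.55. Falling under that bound therefore does not by itself mark arrays of 1 line. If both labels are right, a mean identity difference of 4.34 argues against descent of FarageX1 from Farage. It lay above the 5th percentile of pairs of lines (1.24), with 766 of 780 pairs closer. If the arrays of either line hold other cells, these values say nothing about that descent. Open remain which of the names is right and whether GZMA (2.2 in FarageX1, 6.55 in NU-DHL-1), UGT8 (3.35 and 7.28) and PEG10 (2.33 and 6.08) reflect different cultures or sublines.

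Farage and OCI-Ly19, in different array sets, differed in 531 genes, and both lacked signal for the mismatch repair gene MSH6 (1.58 and 1.81). The identity genes differed by 0.74, over the bound of 0.55 from SU-DHL-4 arrays of different sets, but by an excess (0.19, SE 0.32 over 17 genes) within its spread, and 8 of 780 pairs of lines lay below 0.74. SU-DHL-4 replicate 1 against replicates 2 to 5, the only arrays of 1 line in different sets, had r of 0.971 to 0.972 and 718 to 878 genes at least 2 log2 units apart, against 0.97 to 0.972 and 858 to 936 for Farage and OCI-Ly19, but SU-DHL-4 arrays also parted within set B (642 to 663 genes between replicates 2 or 3 and 4 or 5), so the bound may carry a difference between cultures and be too wide. Cells of 1 line and a shared NF-kB and B-cell surface programme of different lines therefore cannot be told apart, since without the fixed lists and the 768 genes called in both lines the lowest correlation was 0.971, against 0.97 for the highest other pair across sets, a distance (8e-04) below the range of the 2 array pairs (0.002). HLA-DQB1 (2.13 in Farage, 9.54 in OCI-Ly19), RNF183 (2.15 and 9.77) and GPR146 (2.93 and 10.78) differed most with OCI-Ly19 higher.

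The array sets were weighed as the source of the differences between lines. With 1 array per line, so that all pairs have equal power, pairs within a set differed in a median of 1443.5 genes (380 pairs), above the lower quartile of pairs across sets (1321.75) and below their median (1662.5); with all arrays, where set B has more per line, these values were 1655, 1503 and 1889. The set is thereby excluded as the whole cause of these counts, while a part is left open. SU-DHL-4 replicate 1 differed from replicates 2 to 5 in 491 genes, but this does not isolate the set, since 642 to 663 genes lay at least 2 log2 units apart between SU-DHL-4 arrays within set B, against 718 to 878 across sets. For DoHH2 and SU-DHL-4, 512 genes apart, no biological explanation was tested.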

How the results depend on the processing

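The array set block, the comparisons within an array set, the spread from SU-DHL-4 alone, the omission of FarageX1 and the use of 1 array per line were chosen after seeing the data. Of 15760 values of the 336 named results under the alternatives set before, 15474 kept their direction and side of the threshold. Another 283 were no longer past it, 2 became so and 1 turned. Most of the 15760 values come from leaving out 1 array at a time, which ended few calls. Camera with an estimated correlation ended 50 of 122 named list shifts. A mean of at least 6 ended 42 of 113 and a mean of at least 4 ended 27 of 113. The 1 value that turned was for the fibroblast and stromal markers in A4_Fukada (adjusted p = 0.761 with genes of a mean of at least 4, 0.141 to 0.495 under the other alternatives that ended the call). Of that list 3 of 11 members are left with the filter at 4 and 1 with that at 6. Leaving out 1 array at a time gave 14452 to 17951 genes among lines (11184 to 11308 with a range of 2), 1754 to 2043.5 for pairs of lines, 1173 to 1371 for 1 line against the others, 1734 to 2215 for FarageX1 against Farage, 448 to 466 list shifts and 14 to 14 fixed pairs. MCM7 among lines was lost without OCI-Ly19 replicate 2 (adjusted p = 0.0519).

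Filters leave fewer genes to test, so their counts are lower by construction, and they remove the members of lists that are at the floor in most lines (1 of 14 anaplastic large cell lymphoma genes is left with a mean of at least 6, and 0 of 11 myeloid markers). With a mean of at least 4 there were 9572 genes among lines, 290 list shifts and 6 of 9 fixed pairs. With a mean of at least 6 there were 7959 genes among lines, 7180 of them with a range of 2, 1186.5 for pairs of lines, 782 for 1 line against the others, 249 list shifts and 4 of 7 fixed pairs. Over only lines with more than 1 array, which are fewer, there were 227 list shifts, 7 of 8 fixed pairs and 0 of 13 correlations; those counts alone do not show weaker relations. The plain test against 0 asks for no minimum difference and gave 5212.5 for pairs, 6094.5 for 1 line and 8066 for FarageX1 against Farage. Camera with an estimated correlation, which widens the error of each list, gave 198 list shifts. With the mean of all probe sets 1 correlation passed; the cause was not tested.

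The spread from SU-DHL-4 alone gave 3918 genes among lines, 3221 with a range of 2, 446 for pairs, 201.5 for 1 line and 506 for FarageX1 against Farage. It has few residual arrays and holds a set difference, and the cause was not tested further; 34 of 111 named genes among lines and 17 of 122 list shifts were no longer past the threshold. A replicate block gave 13624 genes among lines, 1907.5 for pairs, 1308 for 1 line, 2108 for FarageX1 against Farage, 464 list shifts and 15 fixed pairs. Shared replicate numbers showed no common deviation (median r of -0.005 over 153 pairs of 18 lines, -0.281 to 0.208). Quantile normalization ended 10 of 122 named list shifts and centring 19. Against the mean of the other lines, quantile normalization moved the share of higher genes across 50% in 5 lines, FarageX1 (41.8 to 52.9%), OCI-Ly19 (46.7 to 57.6%), NU-DUL-1 (43.8 to 50.1%), RC-K8 (48.4 to 50.7%) and TK (44.4 to 50.7%). Centring did so in 7 lines, SCC-3 (57 to 47%), DB, MHH-PREB-1, NU-DUL-1, RC-K8, RL and TK, with a median difference over genes of -0.32 in SCC-3 to 0.14 in RL. Genes near the floor limit what these arrays resolve.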

Other observations

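None of the values for shared genes in the next paragraph comes from a test set before the data were examined; the label splits were.

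Some pairs of lines shared genes that set both apart from all 38 others by at least 2 log2 units, which 199 of 780 pairs did for at least 1 gene (median 0). SCC-3 and SU-DHL-1 shared 59 (52 higher, 7 lower), SCC-3 and SR 34, and SR and SU-DHL-1 32, the lines with the anaplastic large cell lymphoma genes higher. A3_Kawakami and A4_Fukada shared 62 (47 higher, 15 lower), and both had the plasma-cell list higher and the germinal-centre list lower. Farage and OCI-Ly19 shared 25 (20 higher, 5 lower). The labels give no relation between any of these lines.

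NU-DHL-1 has arrays with the replicate numbers 3 and 4 and none with 1 or 2. DoHH2, with the fewest genes differing from the mean of the other lines (608), was nearest to SU-DHL-4 replicate 1 (r = 0.969), as was WSU-DLCL2 (r = 0.967). SR, in set A, was nearest to SU-DHL-1 in set B (r = 0.935), and Toledo to NU-DUL-1 (r = 0.959). BCL2 read 14.23 in RI_1 and 10.44 in Farage by the brightest probe set, and 8.31 and 3.33 by a dimmer one; this pair of values was not tested.

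Shuffled labels were used to ask whether chance can give such counts. The real labels gave 15088 genes among lines, and of 100 splits, the real one included, 1 gave as many; the highest other split gave 1711. Random assignment of arrays to lines thus did not give such a count. This shows only that arrays of 1 line were alike, which their correlations had already shown and which may be technical. For SU-DHL-4 against the mean of the other lines the real 5 arrays gave 1260 genes, and of 100 splits 1 gave as many, the highest other giving 1. Shuffling mixes lines and raised the median within-line SD from 0.163 to between 0.497 and 0.558, so the low counts of the other splits follow from the construction and decide nothing for SU-DHL-4.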
